A study of Mus musculus with 6 samples.

How the data were processed

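MicroRNAs were measured by SYBR Green real-time PCR arrays in osteoclasts, the bone-resorbing cells of the myeloid lineage, which had been taken from mouse bone marrow by magnetic sorting for the surface markers OSCAR and CTR. Per the labels, 3 samples came from mice with a knockdown of osteoclast miRNAs (OCmiR-KD, here knockdown) and 3 from control mice (OCmiR-Intact, here intact). Per the labels' protocols, total RNA was taken up in Trizol, reverse transcribed with the QuantiMir kit and amplified for 40 cycles on a ViiA7 instrument. The design text speaks of RNA of 3 mice per group being pooled, while each group holds 3 samples. It is therefore not settled whether the 3 samples of a group are 3 mice or repeat measurements of a pool, and the p-values measure only the spread between these samples, which may be technical.

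The authors deposited 3 series tables. The first holds values headed as raw threshold cycles (Ct, the cycle at which fluorescence crosses a set threshold, so that 1 cycle less stands for about 2 times as much template) for 717 wells on 2 plates. The second holds 709 miRNA assays on a log2 scale as delta Ct, which the authors made by subtracting the Ct of U6, a small nuclear RNA used as reference, in the same sample and plate. This was checked on the values: deposited Ct minus deposited delta Ct is 1 constant per sample and plate and equals the Ct of 1 well on each plate. The third is the authors' deposited table of fold changes, intact over knockdown. Its values lie between 0.99958 and 1.0005 times the folds recomputed from the mean delta Ct. The rule by which a Ct became Null, the Ct threshold and the amplification efficiency are not given in the sources used here. Of the 8 wells that stand only in the Ct table, 6 hold values: the U6 well of each plate and 4 control wells whose names are not given in the sources used here. The IDs of 48 wells in plate row E had been turned into numbers in scientific notation and were restored. All per-sample columns matched a sample's labels. In 88 assays, however, 2 to the power of minus the difference of Ct and plate 1 U6 averages 1 to within 0.001 over the 3 knockdown samples, including 10 of 10 on plate 2. Their Ct values therefore cannot be plain readings, and which step set them is not given in the sources used here. Tests treat the 3 values of a group as independent, which values with a fixed mean are not.

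Of the 709 assays, 95 (13.4%) had a value in all 6 samples, 614 were Null in all 6, and 0 were Null in only some samples. Only the 95 could be compared. The level of a miRNA is minus delta Ct, in log2 units relative to U6, which assumes doubling in each cycle. Levels of different assays also depend on their primers, so an order of miRNAs by level or Ct is one of assay readings, not of abundance. An assay was tested if its Ct was under 35 in at least 3 samples, a rule that all 95 met. Knockdown was compared with intact with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, no covariate), two-sided, with Benjamini-Hochberg adjustment over the 95 assays and a threshold of 0.05. Sample medians and counts of detected assays were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. A PCR array has no read depth. The number of samples limits the precision, and the median residual SD of an assay was 0.82 log2 units.

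There were 21 lists of miRNAs, fixed before the data were examined: osteoclast-promoting, osteoclast-restraining, myeloid and macrophage, erythroid, lymphoid, endothelial and megakaryocyte, stromal and osteoblast-lineage, muscle, neural and epithelial miRNAs, the let-7 and miR-98 family, the miR-17-92 family clusters, the miR-15/16 family, the miR-23/27/24 clusters, the miR-29 and miR-30 families, the miR-34 and miR-449 family, the Dlk1-Dio3 imprinted cluster, the embryonic miR-290 and miR-302 clusters, the X-linked testis clusters, the Sfmbt2 intron cluster, and miRNAs made without Dicer or without Drosha. Every assayed arm or star strand of a listed miRNA counts as a member. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, and again with an estimated correlation), which compares a list with the other assays, and with fry, which tests whether a list's members moved on balance one way. The miRNAs named in the text are those past the threshold with all samples of one group above all of the other, up to 15 per direction by size of change, the 5 largest rises and falls in the authors' deposited table, the 5 with the lowest mean Ct in intact osteoclasts, 2 to 4 members with the smallest p of each list described, and the small RNA controls. Any other miRNA named was chosen after its values were seen. The limma step was tested on simulated data built on the same 95 assays, in 20 data sets. It called 88% of assays simulated with a log2 fall of 5, 46.5% at 2 and 8.5% at 1, and 0.692% of unchanged assays.

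Alternatives fixed before the data were examined were non-normalized Ct, the mean of the small RNA control wells, the mean of miRNAs detected in every sample, quantile normalization, 3 filters on Ct, late Ct values set to 35, eBayes with trend and robust estimation, the replicate number as a block, a further limit of at least 2-fold, and leaving out each sample in turn. Leaving out 13 assays with repeated values, using the mean U6 of both plates and keeping only the assays without a knockdown mean of 1 were chosen after seeing the data. Mature sequences are those printed beside the assays in the authors' deposited tables. A measured miRNA within 2 bases of another assay of equal length on the array was taken as uncertain, since primers may read both. There were 23 of these. Assays of unequal length, such as miR-26a and miR-26b, were not compared, so others may be uncertain too. No genome build is named in the sources used here, so no coordinates are given. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly GRCm38.p6, in which 611 of the 709 array names, and 87 of the 95 measured ones, matched a symbol with or without a copy number. A measured miRNA with several gene copies cannot be assigned to one of them. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.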

Results

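The array data cover 3 intact and 3 knockdown samples of sorted OSCAR+CTR+ mouse osteoclasts. The comparison asks which miRNAs, short RNAs that repress messenger RNAs, differed in level when osteoclast miRNAs had been knocked down. No single target of the knockdown is named in the labels, so the miRNAs as a class and the reference RNA are given first. A limit holds for every miRNA difference below. In 88 of the 95 measured assays the 3 knockdown values, on a linear scale relative to U6 of plate 1, average 1 to within 0.001. This holds for 0 of the 95 in intact samples. For miR-144 the 3 knockdown values are 0.137, 0.123 and 2.74, and for let-7a they are 1.96, 0.975 and 0.0638. The knockdown mean of these 88 is therefore no measurement of its own. The word "fell" below means that the deposited intact values lie above it, which does not show a loss of the miRNA. Whether the intact values were scaled as well, which would keep the folds, is not decided.

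U6, the reference, crossed the threshold at a Ct of 29.7 ± 0.443 cycles (SD, n = 3) in intact and 30.4 ± 0.692 cycles (SD, n = 3) in knockdown osteoclasts, averaged over both plates, a delay of 0.729 cycles. The 4 unnamed control wells averaged 32.8 ± 0.561 cycles in intact and 32.9 ± 0.686 cycles in knockdown samples (SD, n = 3 each). The delay of 0.143 cycles averages opposite shifts. These wells moved by -0.571 and 0.823 cycles on plate 1 and by -0.445 and 0.765 cycles on plate 2. The deposited miRNA values lay further apart. The median Ct over the 95 measured miRNAs was 24.7, 25.4 and 25.9 cycles in the intact samples and 31.3, 30.8 and 29.3 cycles in the knockdown samples. The mean delay was 5.09 cycles, with no overlap of the groups (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).

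**Figure D1:**
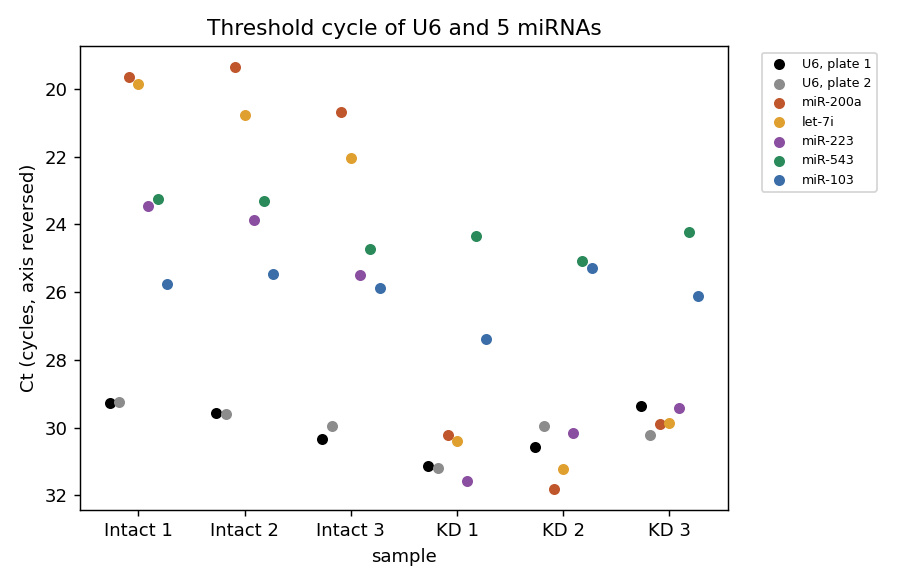
Threshold cycle (Ct, in cycles, axis reversed so that more RNA is higher) of U6 on both plates and of 5 miRNAs in each of the 6 samples, 1 point per well. U6 lies between 29.3 and 31.2 cycles in every sample. miR-200a, let-7i and miR-223 are earlier than U6 in all intact samples and near it in the knockdown samples, while miR-543 and miR-103 stay earlier than U6 in all 6.

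On the U6-relative scale, the deposited miRNA levels as a whole were lower in knockdown osteoclasts. In these, 88 of 95 assays have their linear mean at U6 of plate 1. The median level was 4.39 ± 0.20 log2 units above U6 in intact samples (SD, n = 3) and -0.08 ± 0.16 in knockdown samples (SD, n = 3). The difference of -4.47 log2 units is a 22.2-fold lower median level (exact permutation test, two-sided, p = 0.1). All 3 knockdown medians lay below all 3 intact medians. Counts of assays under the chosen limit were close: 95 assays had a Ct under 35 in each intact sample, against 94, 94 and 95 in the knockdown samples (mean difference -0.667, exact permutation p = 0.4). The late assay was miR-138. At a Ct limit of 32 the mean difference was -12 assays (exact permutation p = 0.1). These counts do not measure detection. The linear knockdown means of 88 assays are fixed at U6 of plate 1, and all 95 were kept for having values in every sample. The shift in levels depends on the reference. Centring each sample on the mean Ct of its detected miRNAs subtracts a mean change of -5.14 log2 units on the Ct scale. Relative to U6 this is -4.53 for assays of plate 1 and -4.29 for those of plate 2. After it the difference of the medians was 0.0453, and after quantile normalization it was -0.0048.

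**Figure D2:**
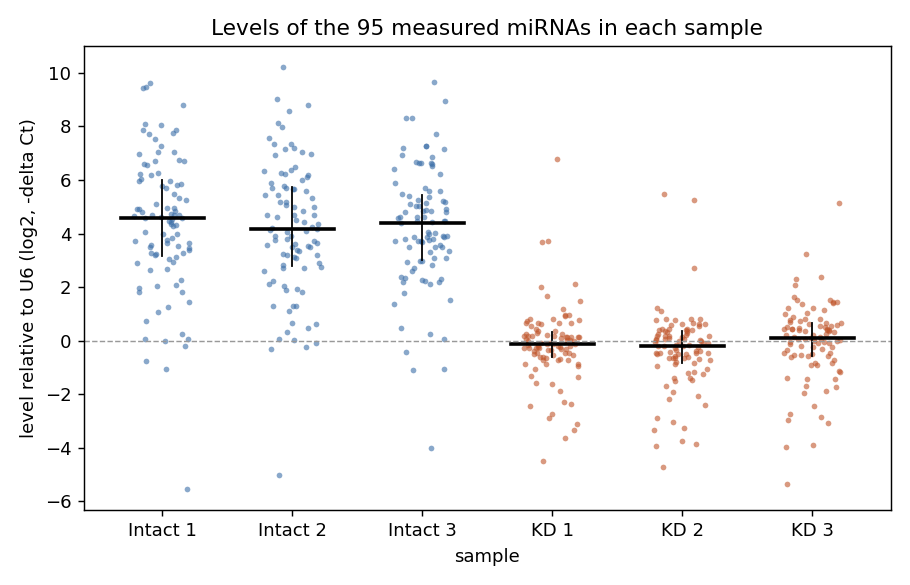
Level relative to U6 (log2, minus delta Ct) of the 95 measured miRNAs in each sample, 1 point per miRNA, with the sample's median (thick line) and quartiles (thin line). The intact medians are 4.58, 4.18 and 4.41, and the knockdown medians are -0.14, -0.20 and 0.10, close to the level of U6 (dashed line).

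Of the 95 miRNAs tested, 80 fell in knockdown osteoclasts, 0 rose and 15 did not pass the threshold (limma, adjusted p under 0.05). All 80 are among the 88 with a knockdown mean of 1, so their p-values and folds describe the deposited values only. Of the 7 other assays, miR-103, miR-138, miR-210, miR-293, miR-470, miR-543 and miR-668, 0 passed. The falls ran from -1.69 to -10.12 log2 units, with a median of -4.95. At least 10-fold falls were seen for 68 miRNAs and at least 100-fold falls for 18. For 78 of the 80, every knockdown sample lay below every intact sample. Chance sets 3 against 3 fully apart, in either direction, 10% of the time. In the authors' deposited table, 92 folds of intact over knockdown were above 1 and 3 were below, with a median of 23.3. Centred on the mean of the detected miRNAs, 39 miRNAs passed, 20 above and 19 below the mean change, and 25 of these were among the 80. Only the 19 below kept the direction of the fall. The rest of the 25, namely miR-222, miR-340-5p, miR-381, miR-451, miR-532-5p and miR-1839-5p, passed above the mean change. After quantile normalization 12 passed, with 5 among the 80. The 4 lower ones were miR-200a, let-7i, let-7g and miR-191, all among the 80. The 8 higher ones were miR-26a, miR-99a, miR-103, miR-210, miR-340-5p, miR-486, miR-543 and miR-668. Of these only miR-340-5p was among the 80, and it passed opposite to its fall. Apart from these 5, no fall named below passed in that setting. Directions below are therefore relative to U6, and each group is also given after this centring. There a value is set against the mean change of the detected miRNAs. The 88 assays with a knockdown mean of 1 make most of that change. A small difference relative to U6 therefore lies above it by construction.

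The miRNA that fell most was miR-200a (UAACACUGUCUGGUAACGAUGU), a member of the miR-200 family that keeps epithelial cells in their state by repressing Zeb1 and Zeb2. It was also the miRNA with the lowest Ct in intact osteoclasts. Its level was 9.84 ± 0.32 in intact and -0.29 ± 1.10 in knockdown samples (SD, n = 3 each), a log2 difference of -10.12 (SE 0.65, limma adjusted p = 1.5e-05). The next 4 in the authors' deposited table also had the next 4 lowest Ct values in intact osteoclasts. let-7i (UGAGGUAGUAGUUUGUGCUGUU) went from 8.84 ± 0.57 to -0.15 ± 0.77, a difference of -8.99 (SE 0.60). miR-200c (UAAUACUGCCGGGUAAUGAUGGA) went from 8.53 ± 0.70 to -0.19 ± 0.87, a difference of -8.71 (SE 0.64). miR-148a (UCAGUGCACUACAGAACUUUGU), which is known to promote osteoclast formation, went from 8.44 ± 1.11 to -0.27 ± 1.12, a difference of -8.71 (SE 0.80). miR-191 (CAACGGAAUCCCAAAAGCAGCUG) went from 8.37 ± 0.50 to -0.004 ± 0.13, a difference of -8.37 (SE 0.49), and its knockdown samples 2 and 3 hold the same delta Ct to the last digit. miR-148a, let-7i and miR-200a each lie within 2 bases of another assay, so their values may include a relative. All 5 also lay below the mean change when the samples were centred on the miRNAs, but after quantile normalization miR-200c (limma adjusted p = 0.0652) and miR-148a (0.167) did not pass. The difference was -10.72 for miR-200a without KD 1 and -9.30 for miR-148a without Intact 3. With the linear knockdown means fixed, the size of a fall mostly follows the deposited intact level (r = -0.971 across the 80 miRNAs). The order of falls is thus largely one of intact values. Where the 3 knockdown values spread widely, their mean log2 level lies further below U6, which enlarges the fall. For miR-30a this level was -1.705 ± 2.81 (SD, n = 3).

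The next 10 falls by size were led by miR-151-3p (-8.25, SE 0.75), let-7f (-7.83, SE 0.93), miR-342-3p (-7.52, SE 0.58), miR-214 (-7.33, SE 0.59) and miR-128 (-7.33, SE 0.85). They were followed by let-7c (-7.29, SE 0.71), the liver miRNA miR-122 (-7.27, SE 0.74), let-7g (-7.11, SE 0.45), miR-143 (-6.83, SE 0.64) and miR-25 (-6.77, SE 0.73). Each of these passed the threshold in limma and lay below the mean change after centring on the miRNAs, but only let-7g passed after quantile normalization (limma adjusted p = 0.033). Leaving out 1 sample moved 7 of these folds by over 1.5 times. Without KD 3 the difference was -7.45 for miR-151-3p, -6.71 for let-7f, -7.92 for miR-128 and -6.59 for let-7c. It was -6.37 for miR-128 and -6.51 for miR-122 without KD 2, and -8.45 for let-7f and -7.87 for miR-122 without KD 1. It was -6.24 for miR-143 without Intact 2 and -7.53 for miR-25 without Intact 3.

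**Figure D3:**
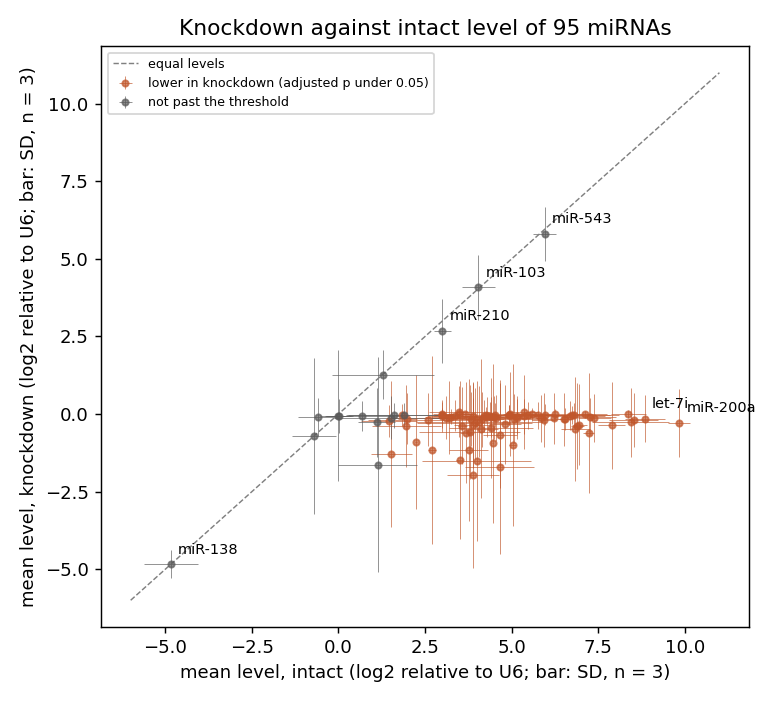
Mean level in knockdown (vertical) against intact (horizontal) samples for 95 miRNAs, both in log2 units relative to U6, with SD bars over 3 samples per group. The 80 miRNAs that fell on this scale (orange) spread widely in intact samples but lie in a band near U6 in knockdown samples. There their linear means are 1 relative to U6 of plate 1. miR-543, miR-103, miR-210 and miR-138 lie near the line of equal levels. Centred on the miRNAs, the last 4 lie above the mean change, as values near that line do by construction.

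Among miRNAs that promote osteoclast formation, 8 of 8 measured members fell, with a median of -5.50. miR-214 fell by 7.33, and miR-148a fell by 8.71. miR-183 fell by 6.00 (SE 0.56), from 5.97 ± 0.77 to -0.03 ± 0.34, and miR-223, a myeloid miRNA, fell by 5.50 (SE 0.53), from 5.46 ± 0.54 to -0.04 ± 0.43 (SD, n = 3). Knockdown samples 2 and 3 hold the same delta Ct of miR-183, as they do of miR-186 and miR-185 below. Centred on the miRNAs, the group's median was -0.97, with 2 members below the mean change (miR-214 and miR-148a) and 0 above it. Among miRNAs that restrain osteoclast formation, 3 of 4 measured members fell. These were miR-186 (-3.48, SE 0.48), miR-145 (-3.97, SE 0.61) and miR-340-5p (-1.88, SE 0.47), all of which reversed to above 0 when centred on the miRNAs. miR-26a had a difference of -0.75 (95% interval -2.40 to 0.91) that did not pass, and with miR-340-5p it lay above the mean change after centring. Adjusted over the list alone, the counts were 8 of 8 and 3 of 4.

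Among myeloid and macrophage miRNAs, 7 of 7 fell, with a median of -5.50, among them miR-342-3p, miR-223, miR-24 (-4.95, SE 0.48) and miR-22 (-3.95, SE 0.51). The values of miR-24 repeat those of miR-199a-3p, as given below. Centred, the median was -0.97, only miR-342-3p passed, below the mean change, and miR-22 reversed to 0.58. Of 3 erythroid miRNAs, miR-144 (-4.98, SE 1.15) and miR-451 (-2.14, SE 0.57) fell. Intact samples 1 and 3 hold the same delta Ct of miR-144. miR-486 stood at 0.49 (95% interval -0.83 to 1.81) and did not pass. Centred, miR-451 and miR-486 lay above the mean change and the erythroid median was 2.39. All 4 measured lymphoid miRNAs fell, namely miR-185 (-4.27, SE 0.49), miR-181d (-4.44, SE 0.60), miR-150 (-5.39, SE 1.16) and miR-181a (-2.81, SE 1.11). Centred on the miRNAs their median was 0.18, miR-185, miR-181d and miR-181a reversed to above 0, and 0 of the 4 passed. Without KD 3 the difference was -3.93 for miR-150, -6.44 for miR-144 and -4.16 for miR-181a. Without KD 2 it was -6.27 for miR-150 and -4.20 for miR-144, and the fall of miR-181a did not pass (limma adjusted p = 0.15). Without KD 1 it was -5.98 for miR-150 and -4.28 for miR-144. The call of miR-181a (limma adjusted p = 0.044) was lost when any sample other than KD 3 was left out. Of 2 endothelial and megakaryocyte miRNAs measured, 1 fell (miR-126-3p, -4.59, SE 0.72), and centred 1 lay above the mean change, miR-99a. The counts over each of these lists alone were equal to those over all assays.

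Among miRNAs of stromal cells and the osteoblast lineage, 8 of 8 fell, with a median of -4.46, led by miR-214, miR-143, miR-199a-3p (-4.95, SE 0.48) and miR-100 (-5.13, SE 0.72, or -4.44 without KD 3). Centred, the median was 0.07, with miR-214 and miR-143 below the mean change. The Ct values given for miR-199a-3p (ACAGUAGUCUGCACAUUGGUUA) and miR-24 (UGGCUCAGUUCAGCAGGAACAG) are identical in all 6 samples although the sequences differ, so at most 1 of these can be counted as a measurement of its own. Among epithelial miRNAs, 6 of 6 fell, with a median of -6.36, including miR-200a, miR-200c, miR-183 and miR-203 (-6.73, SE 0.65). Centred, the epithelial median was -1.83, with miR-200a, miR-200c and miR-203 below the mean change. Of 2 muscle miRNAs measured, 1 fell (miR-1, -4.31, SE 1.01, with equal delta Ct in knockdown samples 2 and 3). Its intact level was 4.06 ± 1.83 (SD, n = 3). Centred, miR-1 reversed to 0.22 without passing, and 1 lay above the mean change, miR-206. The neural list had 1 measured member, miR-128, which fell. Adjusted over the list alone, these counts were unchanged for the 4 lists.

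The let-7 and miR-98 family, which represses growth-promoting genes such as Hmga2, fell as a whole. Counting the star strand let-7d*, 10 of 10 measured members passed, with a median of -6.37. let-7b fell by 6.70 (SE 0.57) and let-7e fell by 5.99 (SE 0.54), beside let-7g and let-7i above. Most members differ by 1 or 2 bases, and their separate values are uncertain for that reason. Centred, the family median was -1.84, and let-7b, let-7c, let-7f, let-7g and let-7i lay below the mean change. All 5 measured members of the miR-17-92 family clusters fell, among them miR-25, miR-92a (-3.66, SE 0.45), miR-106b (-3.95, SE 0.68) and miR-93 (-2.77, SE 0.93), though the last 3 reversed to above 0 when centred. miR-93 lost its call (limma adjusted p = 0.023) without Intact 1, Intact 3, KD 1 or KD 2, and its difference was -3.76 without Intact 2 and -2.12 without Intact 3. miR-106b was at -4.64 without KD 3. In the miR-23/27/24 clusters 3 of 3 fell, namely miR-23a (-6.11, SE 0.59), miR-24 and miR-27b (-4.24, SE 0.95), and miR-27b reversed to 0.29 when centred. In the miR-29 and miR-30 families the 3 measured members were all miR-30, and all fell: miR-30c (-3.42, SE 0.56), miR-30a (-6.36, SE 1.33) and miR-30d (-4.36, SE 0.98), with miR-30c at 1.11 and miR-30d at 0.17 when centred. Without KD 1 the difference was -7.95 for miR-30a and -5.23 for miR-30d. It was -5.29 for miR-30a without KD 2, -5.19 for both miR-30d and miR-27b without Intact 2, and -4.83 for miR-27b without KD 3. Centred on the miRNAs, 1 of the miR-17-92 members passed, below the mean change (miR-25), and 0 of 3 in each of the other groups. No member of the miR-15/16 family or of the miR-34 and miR-449 family had a value, 0 of 12 and 0 of 8 assays.

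In the Dlk1-Dio3 imprinted cluster, 73 assays were on the array and 5 had values. Of these, miR-382 (-5.26, SE 0.55), miR-381 (-3.06, SE 0.52) and miR-134 (-4.92, SE 1.08) fell, and miR-134 was at -6.17 without KD 3 and at -3.93 without KD 1. miR-543 kept a level of 5.96 ± 0.33 in intact and 5.80 ± 0.86 in knockdown samples (SD, n = 3 each), a difference of -0.16 (95% interval -1.53 to 1.21). miR-668 had a difference of -0.02 (95% interval -1.95 to 1.91). Centred, miR-381, miR-543 and miR-668 lay above the mean change. Of miRNAs made without Dicer or without Drosha, the enzymes that cut most miRNA precursors, 4 of 4 fell. These were miR-320 (-5.24, SE 0.51), miR-1981 (-3.41, SE 0.67), the Dicer-independent miR-451, and miR-1839-5p (-1.69, SE 0.59). Their median was -2.78, or 1.63 when centred, where miR-451 and miR-1839-5p lay above the mean change and miR-1981 was at 0.88. Without Intact 2, Intact 3 or KD 1, miR-1839-5p lost its call. Relative to U6 of plate 1, knockdown samples 2 and 3 of miR-1981 hold the same value. The single measured members of the embryonic and X-linked testis clusters, miR-293 (0.01, 95% interval -2.73 to 2.75) and miR-470 (-0.03, 95% interval -2.37 to 2.31), did not pass, and that of the Sfmbt2 intron cluster, miR-669h-3p, fell by 4.66 (SE 0.81). Centred, the first 2 lay above the mean change and the last was at -0.14. Adjusted over each list alone, the counts for the families and clusters were equal to those over all assays.

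In the set tests, 13 of the 21 lists had at least 3 measured members. All 13 moved down on balance (fry, largest adjusted p = 0.0191), which the fixed knockdown means build in wherever intact levels lie above U6. Compared with the other miRNAs, 0 lists stood apart (camera with the preset correlation, smallest adjusted p = 0.318; with an estimated correlation, smallest adjusted p = 0.87). At an unadjusted p under 0.05, camera with the preset correlation gave 1 list, the erythroid miRNAs, with a smaller fall than the rest (p = 0.0354). With an estimated correlation it gave 0. As most knockdown means are fixed, camera compares mainly deposited intact values. Whether these were scaled as well is not decided, so camera does not show which groups the knockdown affected.

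The authors' deposited table gives folds below 1 for 3 miRNAs, miR-486 (0.712), miR-103 (0.968) and miR-293 (0.995). Its next lowest are miR-138 and miR-668. miR-103 stood at 4.03 ± 0.47 in intact and 4.08 ± 1.05 in knockdown samples (SD, n = 3 each), a difference of 0.05 (95% interval -1.48 to 1.57). Its assay lies within 2 bases of that of miR-107. miR-138 stood at -4.84 ± 0.78 and -4.84 ± 0.45 (SD, n = 3 each), with a mean Ct of 34.6 and 35.2 cycles. miR-210, a miRNA induced by hypoxia and chosen after its values were seen, stood at 3.00 ± 0.24 and 2.67 ± 1.03 (SD, n = 3 each), a difference of -0.33 (95% interval -1.78 to 1.13). Centred on the miRNAs, miR-103, miR-138, miR-210, miR-486 and miR-543 all lay above the mean change. A small difference relative to U6 gives this by construction, since assays with a knockdown mean of 1 make most of that change. Of these miRNAs only miR-486 has a knockdown mean of 1 itself. The intervals leave room for changes of more than 2-fold in either direction for miR-103 and miR-543, so no statement of equal levels follows from the missed threshold.

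Over all 95 miRNAs the deposited mean levels had an SD of 2.35 log2 units in intact and 1.05 in knockdown samples, the latter kept low by the fixed means. Any pair of intact samples correlated across miRNAs with r between 0.884 and 0.907. Knockdown samples 1 and 2 correlated with r = 0.68, and knockdown sample 3 with r = 0.00869 and 0.0703 against these samples. Among the 88 miRNAs with a knockdown mean of 1, the rank correlation was 0.0701 for samples 1 and 2, -0.702 for 1 and 3 and -0.641 for 2 and 3. A fixed mean of 3 values builds in negative correlations, and their mean, -0.424, is what it gives.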

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

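Leaving out the 13 assays with repeated values, using the mean U6 of both plates and keeping only the 7 assays without a knockdown mean of 1 were chosen after seeing the data. With these 7 alone the count was 0 and the difference of sample medians 0.056. Tested among all 95, their differences of -0.33 to 0.05 log2 units did not pass either, and all 80 that fell have a knockdown mean of 1. No other setting undoes those fixed means. The count of 80 fallen miRNAs kept its direction and stayed within 1.5 times under non-normalized Ct (84), the control wells (82), the filters, late Ct values set to 35 and the 2-fold limit (80 each), trend and robust estimation (78), without repeated values (69 of 82 tested) and with the mean U6 (79), and it ranged from 75 to 81 when 1 sample was left out. When centred on the mean of the detected miRNAs 39 passed, of which 19 fell, and after quantile normalization 12 passed, of which 4 fell. Both settings remove a common shift by construction. The difference of sample medians, -4.47, was -5.09 on non-normalized Ct and -4.80 against the control wells, where the U6 delay is not or only partly subtracted. It was 0.0453 after centring on the miRNAs and -0.0048 after quantile normalization, and ranged from -4.57 to -4.37 when 1 sample was left out. The difference in assays under the Ct limit, -0.667, was -12 at a limit of 32 and 0 at 38, and ranged from -1 to -0.5 without 1 sample. With most knockdown means fixed at U6, it does not measure detection. The count of lists standing apart in camera was 0 in every setting with lists to test. The 7 assays alone left no list with at least 3 measured members.

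With the replicate number as a block (replicate block), 82 miRNAs fell, 80 of them shared with the fit without it. The deviations of same-numbered samples correlated at 0.025, 0.101 and 0.0809, not all over 0.1, so the numbers were not taken to pair the samples. Knockdown sample 1 correlated no better with intact sample 1 than with intact sample 2 (0.027).

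Of the 54 named miRNAs, 21 changed sign after centring on the miRNAs, with values of 4.53 for miR-138, 4.51 for miR-668, 1.05 for miR-186, 0.56 for miR-145, 2.65 for miR-340-5p, 3.78 for miR-26a, 0.58 for miR-22, 2.39 for miR-451, 0.26 for miR-185, 0.093 for miR-181d, 1.72 for miR-181a, 0.87 for miR-92a, 0.58 for miR-106b, 1.76 for miR-93, 0.29 for miR-27b, 1.11 for miR-30c, 0.17 for miR-30d, 1.47 for miR-381, 4.37 for miR-543, 0.88 for miR-1981, 2.60 for miR-1839-5p. After quantile normalization 17 changed sign, with 4.37 for miR-668, 0.74 for miR-186, 0.64 for miR-145, 2.13 for miR-340-5p, 3.30 for miR-26a, 0.28 for miR-22, 1.66 for miR-451, 0.15 for miR-185, 0.72 for miR-181a, 0.58 for miR-92a, 0.092 for miR-106b, 1.11 for miR-93, 0.79 for miR-30c, 1.01 for miR-381, 4.53 for miR-543, 0.74 for miR-1981, 2.04 for miR-1839-5p. Of the 47 named miRNAs that fell, 17 still fell after centring, 13 were below 0 without passing and 17 were at or above 0. After quantile normalization these numbers were 4, 29 and 14. Among these 47, outside these 2 settings none changed sign, and calls were lost only for miR-181a, miR-93 and miR-1839-5p, with fewer samples, another variance estimate or, for miR-181a, the mean U6; the cause was not tested. Leaving out 1 sample moved the fold of 19 of the 47 by over 1.5 times, at most by 3.01 times (miR-30a without KD 1). Fallen miRNAs mentioned outside these 47, such as miR-1, miR-126-3p, miR-142-5p and miR-669h-3p, are not in this count. The number of samples limits the precision. In the simulated data, which did not vary that number, 8.5% of log2 falls of 1 were called.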

Other observations

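The 95 assays with values in intact osteoclasts included miRNAs best known from other tissues. miR-122, a liver miRNA, read 6.90 ± 0.19 log2 units relative to U6 (SD, n = 3), and miR-192 and miR-215, known from gut and liver, read 4.29 and 5.06. Readings of different assays depend on their primers and are not ranked here. miR-122, miR-192 and miR-215 are among the 88 assays with a knockdown mean of 1. If their intact values were scaled as well, these are not levels relative to U6. Among immune miRNAs, miR-155, miR-146a and miR-142-3p were Null in all 6 samples. miR-142-5p, the other arm of the miR-142 hairpin, had values and fell by 5.86 in knockdown samples (SE 1.37). Its knockdown values spread widely, at 0.0798, 0.0741 and 2.85 on a linear scale relative to U6 of plate 1. miR-16, miR-17, miR-20a, miR-19b and miR-29a were Null in all 6 samples as well. These miRNAs, other than the ones named by the fixed rule, were chosen after their values were seen.

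Some neighbouring miRNA genes differed in whether a value was given. By a RefSeq gene table of assembly GRCm38.p6, 41 measured miRNAs had another assayed miRNA gene within 10 kb of at least 1 of their gene copies, among the 87 of 95 measured names that matched the table. For 16 of the 41 every such neighbour was Null in all samples, and for 25 at least 1 had values. miR-200a had values and its neighbours miR-200b and miR-429 were Null. The same held for miR-200c and miR-141, and for miR-183 with miR-182 and miR-96. Of the neighbours of miR-23a, miR-27a was Null and miR-24 had values, though miR-24 has 2 gene copies. In contrast miR-25, miR-93 and miR-106b, as well as miR-191 and miR-425, had values together. Star strands had values in 5 of 119 assays, against 90 of 590 for the others.

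All tests of explanations here were chosen only after the result was seen. The first pattern is that the knockdown values of 88 of the 95 assays, on a linear scale relative to U6 of plate 1, average 1 to within 0.001 (at most 0.000315 away), though single values spread widely, as 0.137, 0.123 and 2.74 for miR-144. When knockdown values were shuffled between assays, 0.213 assays did so on average and at most 3 in 10000 shuffles, so neither a background signal nor a loss of each miRNA to a similar low level, the biological explanation, gives these means. Knockdown values set to a mean of 1 per assay fit them: 10 of 10 plate 2 assays average 1 relative to U6 of plate 1, and 0 relative to U6 of their own plate, although their deposited delta Ct uses the latter. The values deposited as Ct for these assays are then not plain instrument readings. The tables do not decide whether the intact values were divided by the same factor, which would keep the folds, or not, which would leave the folds without meaning, and no test here can show how much of any miRNA was lost.

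The second pattern is that among these 88 assays knockdown samples 1 and 2 had rho = 0.0701, while sample 3 had rho = -0.702 and -0.641 with them. The mean of the 3, -0.424, needs no cause beyond the fixed means, since random assignment of the 3 values of each assay to the samples gave -0.42 to -0.439. The highest minus the lowest rho, 0.772, was as large in few of 2000 such assignments (permutation p = 0.001, assays taken as independent), so the fixed means alone do not set apart sample 3. What does was not tested, and differences in mice or handling were not tested either.

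The third pattern is values repeated to the last deposited digit. Equal delta Ct values between samples of the same assay occurred 9 times, 6 of these between knockdown samples 2 and 3. Over all 15 sample pairs 0.33 are expected from how often values lie within 0.1 cycles, which argues against chance coincidence. The exact Poisson p of 9 or more is 9.51e-11. Equal Ct values occurred 0 times. The 7 delta Ct repeats between knockdown samples lie in plate 1 assays with a mean of 1, on the scale of that mean. The 2 between intact samples are in miR-144 and miR-152. Relative to U6 of plate 1, miR-1981 of plate 2 also repeats, at 0.848 in knockdown samples 2 and 3. It is not in these counts, the position test or the 13 assays left out for repeats. In position, 8 of the 9 assays with equal delta Ct lie among the 16 measured ones in a single stretch of plate 1. The stretch was chosen after seeing it (Fisher's exact p = 8.75e-07), and miR-1981 lies outside it. miR-24 and miR-199a-3p repeat each other's Ct in all 6 samples, and miR-361 and miR-99b* in all 3 knockdown samples though on different plates. One target for miR-361 and miR-99b* would keep their Ct difference as constant in intact samples, where it varies by 0.539 cycles and is at least 5.29. For miR-24 and miR-199a-3p, equal in 6 of 6 samples on 1 plate, no wells of one target on one plate are there to compare, so one target for both stays open. What produced the repeats stays open, and no biological explanation was tested.

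Among the 10 splits of the 6 samples into 3 and 3, 1 split, the real one, gave 80 miRNAs past the threshold, and the highest of the others gave 0. With knockdown means set within the real group, and scaling of the intact values not decided, this split does not show a biological difference.

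In the deposited intact values U6 crossed the threshold later than most assays, and 91 of the 95 had a mean level above U6. Whether the intact values of assays with a knockdown mean of 1 were scaled is not decided, so this counts deposited values only. Of the 15 miRNAs not past the threshold, 6 had a limma adjusted p above 0.9, and 8 of the 15 have a knockdown mean of 1.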
